A study of Caenorhabditis elegans with 15 samples.

How the data were processed

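Messenger RNA was sequenced from whole Caenorhabditis elegans on day 1 of adulthood, grown without stress. There were 3 strains with 5 biological samples each: the wild-type strain N2, a fndc-1(rny14) mutant and an atfs-1(tm4525); fndc-1(rny14) double mutant. Per the labels' protocols, the bacterial food was removed, the worms were frozen in liquid nitrogen and RNA was taken with Trizol. The labels name both an Illumina TruSeq RNA kit and the TruSeq Stranded mRNA kit. They do not describe separate cultures, so p-values measure the spread between these samples, which may be partly technical.

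The authors deposited a table of raw counts per gene, 1 column for each of 15 libraries, with no normalization. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.6.0c, Subread 1.6.1 with featureCounts and the genome build WBcel235 were used. The strand setting of the counting, its annotation release and its handling of reads that map to several places are not given in the sources used here. Counts of genes that overlap, lie antisense to each other or have near-identical copies are therefore uncertain. The table held 20191 genes, of which 789 had no count in any library. Gene positions came from the Ensembl release 115 annotation of WBcel235, to which 19832 gene names matched and 359 did not.

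Total counts ranged from 46984106 to 61921123 per library. Replicates were compared by a chi-square of their counts over genes with at least 50 counts in the pair. The lowest value was 8.07 per gene, so no library repeated another of its own strain within sampling noise. Libraries of different strains were not compared in this way.

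Genes were kept by filterByExpr with the strain as group, which left 15032. Library sizes were scaled by TMM factors, and CPM values were computed from the counts and the scaled sizes by edgeR's cpm function. The main test was the two-sided quasi-likelihood F-test of edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3). It was fitted to all 15 libraries with strain means and no covariate, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors (SE) are the size of the log2 fold change divided by the square root of its F value, and 95% intervals take the normal quantile of that SE. A set of 35 gene lists was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, with adjustment over the lists. Of the list members, 5 names were not in the table. Adjusted p-values come from these tests unless another is named.

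The comparisons, lists, tests, other settings and the rule for named genes were fixed before the data were examined. The rule took fndc-1, atfs-1, hsp-6 and hsp-60 in each comparison. It then took the 6 largest rises and the 6 largest falls among genes past the threshold whose strains did not overlap, with a mean of at least 5 CPM in the higher strain and a gene-class symbol. It also took up to 3 members past the test, by adjusted p, from each of the 6 lists with the smallest camera p among lists that passed or held at least 3 members past the test. For genes past the threshold in both of a pair of comparisons, it took 6 with a gene-class symbol per direction, by the larger of their adjusted p-values.

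Settings changed in turn were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 5 libraries, fits of only the strains compared, the replicate number as a block, camera with an estimated correlation, fry, and leaving out each library in turn. Settings chosen after seeing the data were the sperm list score as a covariate, which fixes the outcome for that list itself, leaving out double-mutant libraries 2 and 4, and leaving out the genes of 2 chromosome ends.

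The tests were run first on simulated counts with 100 genes changed 2-fold and 100 changed 1.5-fold among 15032. The changed genes were drawn from those above about 1 CPM in wild type, and genes were simulated independently. Recovery at lower counts was not measured. Of the 2-fold genes, 62% were recovered for fndc-1 against wild type, 63% for the double mutant against wild type and 71% for the double mutant against fndc-1. Of the 1.5-fold genes, 29%, 30% and 31% were recovered. Pairs of comparisons share a strain, so for each pair 20 separate simulations drew all 15 libraries at the level of the shared strain, with no change between strains, and the libraries of the shared strain were divided between the comparisons in 20 ways.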

Results

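RNA-seq counts were available for 15 libraries of whole day 1 adult worms, 5 each of wild type, the fndc-1 mutant and the atfs-1; fndc-1 double mutant. FNDC-1 is a mitophagy receptor, and ATFS-1 is a transcription factor of the mitochondrial unfolded protein response. The comparisons ask how loss of fndc-1 alters transcript levels without stress and which part of that difference depends on atfs-1. No atfs-1 single mutant was among the strains. A difference between the double mutant and fndc-1 therefore cannot be told apart from an effect of the atfs-1 mutation alone. Library totals ranged from 46984106 to 61921123 counts, and 15032 genes were tested.

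Libraries of the same strain differed in markers of stage. The sperm list score, its mean centred log2 CPM, was -1.80, -1.76 and -1.86 in wild-type libraries 1, 3 and 5 but 0.76 and 0.46 in wild-type libraries 2 and 4. It reached 2.303 in double-mutant library 4, where the collagen score was 2.26 and the moulting cycle score 1.67. The first principal component held 41.4% of the variance and ran from -57.9 in wild-type library 5 to 111.2 in double-mutant library 4. Double-mutant library 2 lay apart on the second component, at -82.4, with a cytosolic ribosome score of 0.61 and a germline score of -0.79. On that component fndc-1 libraries 1, 2 and 3 lay between -13.9 and -8.94 and fndc-1 libraries 4 and 5 at 26.3 and 27.6. The chi-square per gene was 8.07 to 18.9 within these 2 sets of fndc-1 libraries and 60.5 to 89.1 between them.

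**Figure D1:**
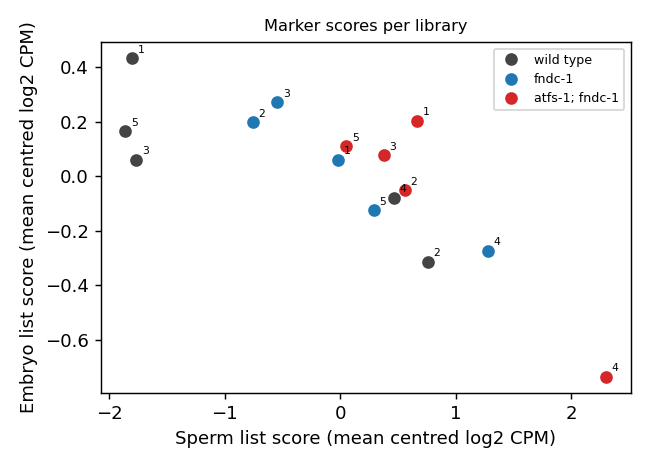
Each point is 1 library with its replicate number, placed by its sperm list score (x axis) and embryo list score (y axis), both mean centred log2 CPM; colours give the strain. Wild-type libraries 1, 3 and 5 lie at sperm scores of -1.80, -1.76 and -1.86 and double-mutant library 4 at 2.303.

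The targeted genes were examined first. The fndc-1 transcript (chromosome II, 11236624 to 11237325, WBcel235) had 40.9 ± 3.83 CPM in wild type (SD, n = 5), 7.39 ± 0.130 CPM in the fndc-1 mutant and 7.95 ± 1.27 CPM in the double mutant. Against wild type its log2 fold change was -2.47 in fndc-1 (SE 0.106, adjusted p = 1.86e-09) and -2.36 in the double mutant (SE 0.105, adjusted p = 1.369e-08). The atfs-1 transcript (chromosome V, 14193663 to 14197700) had 104.0 ± 4.92 CPM in wild type, 93.4 ± 4.66 CPM in fndc-1 and 75.4 ± 4.59 CPM in the double mutant. It was lower in the double mutant than in wild type (log2 -0.46, SE 0.0592, adjusted p = 0.0004443) and than in fndc-1 (log2 -0.31, SE 0.0592, adjusted p = 0.01558). Without fndc-1 library 4 the last call was lost (atfs-1 log2 -0.29, adjusted p = 0.05651), as it was when only these strains were fitted (log2 -0.34, adjusted p = 0.0525). Transcript outside a deleted part can persist, so the atfs-1 level is a limited check of that genotype.

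The mitochondrial chaperone genes hsp-6 and hsp-60, standard reporters of the mitochondrial unfolded protein response, passed the test in none of the 3 comparisons with all libraries. The hsp-6 transcript had 629.3 ± 69.2 CPM in wild type, 681.5 ± 116 CPM in fndc-1 and 825 ± 293 CPM in the double mutant (n = 5 each). Its log2 fold change in the double mutant over wild type was 0.39 (95% interval -0.08 to 0.86, adjusted p = 0.3386). Double-mutant library 2 held 319.3 CPM of hsp-6 and the other libraries of the strain 856.7 to 1048 CPM. Without that library hsp-6 was higher in the double mutant than in wild type (log2 0.58, adjusted p = 0.01148), as it was without double-mutant libraries 2 and 4 (log2 0.53, adjusted p = 0.03934). The hsp-60 means were 416.6 ± 75.8, 532.9 ± 115.4 and 505.1 ± 139 CPM, and its log2 fold change in fndc-1 over wild type was 0.36 (95% interval -0.05 to 0.76, adjusted p = 0.4772).

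**Figure D2:**
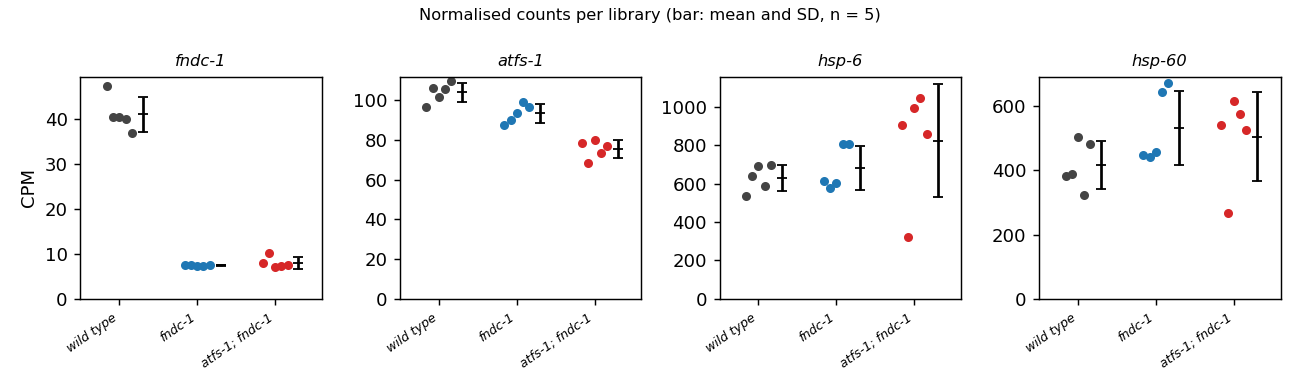
Each point is the CPM of 1 library (y axis, from 0) of the strain on the x axis, with the mean and SD of the 5 libraries beside the points. The fndc-1 transcript lies at 7.39 and 7.95 CPM in the mutants against 40.9 CPM in wild type, and double-mutant library 2 has 319.3 CPM of hsp-6.

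The metallothionein gene mtl-1 fell from 31.01 ± 14.8 CPM in wild type to 4.36 ± 0.541 CPM in fndc-1 (log2 -2.83, SE 0.273, adjusted p = 2.452e-05), and mtl-2 fell from 259.9 ± 41.6 to 154.5 ± 8.10 CPM (log2 -0.75, adjusted p = 0.01068). The cytochrome P450 genes cyp-25A3 (log2 -1.203, adjusted p = 0.0007885) and cyp-25A1 (log2 -1.33, adjusted p = 0.03456), the flavin monooxygenase gene fmo-5 (log2 -0.91, adjusted p = 0.001295) and the F-box gene fbxa-192 (log2 -3.76, adjusted p = 8.339e-10) were also lower. Higher were dct-17 (log2 1.88, adjusted p = 0.0003203), dod-24 (log2 1.46, adjusted p = 0.007195) and pqn-75 (log2 1.05, adjusted p = 0.003127). The cyclophilin gene cyn-5 (log2 1.57, adjusted p = 3.574e-07), tep-1 (log2 1.33, adjusted p = 0.01068) and the SET domain gene set-10 (log2 1.16, adjusted p = 1.809e-05) were higher too and lie at the right end of chromosome I, described with the genes that changed back. The call of mtl-2 was lost without fndc-1 library 2 (adjusted p = 0.05401). The call of cyp-25A1 was lost without any of 10 libraries, namely wild-type 1, 3 and 5, each fndc-1 library and double-mutant 1 and 5 (log2 -1.41 to -1.17, highest adjusted p = 0.1051), and with upper-quartile factors or no filter (highest adjusted p = 0.053).

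In all, 281 genes passed, 178 higher and 103 lower in fndc-1, with 2247 at an unadjusted p under 0.05. Among all 15032 genes tested, the strains did not overlap for 1207 (8.03%), and chance gives 0.794%. They did not overlap for 269 of the 281, which the test selects for separation. The number of genes changed was 736 without double-mutant library 2, 1116 without double-mutant libraries 2 and 4, 630 with the sperm covariate, 575 when only these strains were fitted and 784 with DESeq2. It was 162, 152 and 185 without wild-type libraries 2, 4 and 5, and 149, 146 and 157 without fndc-1 libraries 1, 2 and 3.

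Of the 35 lists, 16 passed camera's test between fndc-1 and wild type, 8 higher and 8 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.3959), and fry called 1, mitochondrial dynamics and mitophagy, which contains fndc-1. That list was lower (median log2 -0.09, adjusted p = 0.00374, and adjusted p = 0.3959 with an estimated correlation), and fndc-1 was the only one of its 16 members past the test over all genes. Adjusted over the list alone, 2 were lower. The list was not tested without fndc-1, the mutated gene.

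The insulin pathway and DAF-16 targets were lower in fndc-1 (median log2 -0.31, adjusted p = 0.0001009, and adjusted p = 0.641 with an estimated correlation). Of 21 members, mtl-1 and mtl-2 were lower and the acid sphingomyelinase gene asm-2 was higher (log2 0.53, adjusted p = 0.04103). Adjusted over the list alone, 9 were lower and 1 higher. The insulin score was -0.14 to -0.090 in fndc-1 libraries 1, 2 and 3 and -0.35 and -0.36 in fndc-1 libraries 4 and 5. The call of asm-2 was lost without any of 10 libraries, namely each wild-type library, fndc-1 libraries 1, 3 and 4 and double-mutant libraries 1 and 3 (log2 0.49 to 0.57, highest adjusted p = 0.1135), and with the sperm covariate (adjusted p = 0.053).

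The list of 12 protein genes of the mitochondrial genome passed as lower in fndc-1, with 1 member lower over all genes (median log2 -0.40, adjusted p = 0.001716, and adjusted p = 0.641 with an estimated correlation). That member was the ATP synthase subunit gene atp-6 (75.5 ± 24.99 CPM in wild type, 43.4 ± 4.51 CPM in fndc-1, log2 -0.80, adjusted p = 0.03826), and 7 members were lower adjusted over the list alone. The score of this list was 0.757 in wild-type library 1, 0.150, -0.031 and 0.163 in libraries 2, 3 and 4, and -0.2837 in library 5. In fndc-1 it was -0.2831 to -0.040, so the strains overlapped. The call of atp-6 was lost without any of 10 libraries, namely wild-type 1, 4 and 5, each fndc-1 library and double-mutant 1 and 5 (log2 -0.85 to -0.66, highest adjusted p = 0.1242), and with upper-quartile factors, no filter or limma-voom (highest adjusted p = 0.06629). The autophagy list was lower (median log2 -0.12, adjusted p = 0.002943, and adjusted p = 0.7148 with an estimated correlation), with 1 of 25 members past the test and 2 lower adjusted over the list alone. That member, atg-3, had log2 -0.24 (adjusted p = 0.03023) and lost its call without wild-type libraries 1, 2, 4 or 5 or fndc-1 libraries 1, 2 or 3 (log2 -0.24 to -0.22, highest adjusted p = 0.1053). The call of atg-3 was also lost with upper-quartile or RLE factors or no filter (highest adjusted p = 0.06506).

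The UDP-glucuronosyltransferase family, whose enzymes conjugate toxins, was higher in fndc-1, with 4 of 62 members higher and 5 adjusted over the list alone (median log2 0.14, adjusted p = 0.003983, and adjusted p = 0.7148 with an estimated correlation). The cytochrome P450 family was lower, with 6 of 64 members lower, and 9 lower and 2 higher adjusted over the list alone (median log2 -0.19, adjusted p = 0.004771, and adjusted p = 0.7148 with an estimated correlation). With the CPM filter the cytochrome P450 family did not pass (median log2 -0.06, adjusted p = 0.08682). The sperm list passed as higher with 0 of 64 members past the test over all genes or adjusted over the list alone (median log2 0.67, adjusted p = 2.291e-06, and adjusted p = 0.8603 with an estimated correlation), and its scores differed within wild type as given above. Leaving out 1 library kept the call but gave a sperm median of 0.41, 1.23, 0.43 and 0.42 for wild-type libraries 1, 2, 3 and 5 and 0.17 for fndc-1 library 4. The median of the cytochrome P450 family was -0.11 without wild-type library 1 or fndc-1 library 5, and that of the UDP-glucuronosyltransferase family 0.091 without fndc-1 library 4. The mitochondrial unfolded protein response list did not pass (median log2 0.03, mean -0.02, adjusted p = 0.8023), with 0 of 16 members past the test over all genes and 1 lower adjusted over the list alone.

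Other lists that passed in fndc-1 had few members past the test. The proteasome (median log2 -0.11, adjusted p = 7.343e-05, and adjusted p = 0.7148 with an estimated correlation) was lower. Also lower were oocyte and eggshell (median log2 -0.11, adjusted p = 0.008654, and adjusted p = 0.8603 with an estimated correlation) and histones (median log2 -0.09, adjusted p = 0.01005, and adjusted p = 0.8603 with an estimated correlation). These 3 lists had 0 members past the test over all genes or adjusted over the list alone. Muscle (median log2 0.17, adjusted p = 0.01962, and adjusted p = 0.8603 with an estimated correlation) was higher. So were hypodermis and seam (median log2 0.38, adjusted p = 0.01962, and adjusted p = 0.7148 with an estimated correlation) and the moulting cycle (median log2 0.15, adjusted p = 0.04593, and adjusted p = 0.8603 with an estimated correlation), and all 3 also had 0 such members. Cytosolic heat shock was higher with 0 of 17 members past the test over all genes, and 5 higher and 2 lower adjusted over the list alone (median log2 0.99, adjusted p = 0.01181, and adjusted p = 0.7099 with an estimated correlation). The heat shock score was 0.52 to 0.63 in fndc-1 libraries 1, 2 and 3, -0.16 and -0.13 in fndc-1 libraries 4 and 5, and -1.29 to -0.42 in wild type. Libraries 4 and 5 also stood apart in the proteasome score (0.026 and 0.069, against -0.10 to -0.077 in fndc-1 libraries 1, 2 and 3) and in that of oocyte and eggshell (0.13 and 0.15, against -0.11 to -0.078). The C-type lectin family was higher with 4 of 129 members higher, and 4 adjusted over the list alone (median log2 0.14, adjusted p = 0.0345, and adjusted p = 0.8603 with an estimated correlation). The call of oocyte and eggshell was lost without wild-type library 3 (median log2 -0.08, adjusted p = 0.05585) and that of muscle without wild-type library 5 (median log2 0.13, adjusted p = 0.08607). The moulting cycle did not pass without wild-type libraries 1, 2 or 3, fndc-1 libraries 2 or 3 or double-mutant library 5 (highest adjusted p = 0.1909), nor the C-type lectin family without wild-type libraries 3 or 5 or fndc-1 libraries 1, 2 or 3 (highest adjusted p = 0.2119). Calls were kept with other medians for oocyte and eggshell without wild-type library 5 (-0.069), the moulting cycle without wild-type libraries 4 or 5 (0.26 and 0.39) and the C-type lectin family without fndc-1 library 5 (0.24). The histones had -0.14 without wild-type library 4, and -0.25 and -0.058 without fndc-1 libraries 3 and 4. With the sperm covariate the C-type lectin family, histones, hypodermis and seam, the moulting cycle, muscle, and oocyte and eggshell did not pass (adjusted p = 0.08798 to 0.3244). Nor did the C-type lectin family with upper-quartile factors, DESeq2, the CPM filter or a fit of only these strains (highest adjusted p = 0.1261), the moulting cycle with upper-quartile or RLE factors or DESeq2 (0.07766), or histones with DESeq2 (0.06346).

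Between the double mutant and wild type, the cuticle collagen genes col-103 (164.8 ± 41.2 CPM in wild type, 456.5 ± 57.4 CPM in the double mutant, log2 1.47, adjusted p = 0.0001077), col-98 (log2 1.51, adjusted p = 0.0001108) and col-80 (log2 1.19, adjusted p = 0.0001992) rose. The UDP-glucuronosyltransferase genes ugt-61 (log2 0.85, adjusted p = 0.000447), ugt-46 (log2 0.82, adjusted p = 0.0006544) and ugt-47 (log2 0.91, adjusted p = 0.00236) rose, as did drd-50 (log2 2.81, adjusted p = 0.0001077) and dod-24 (log2 2.73, adjusted p = 6.97e-05). Lower were cyp-25A1 (log2 -1.63, adjusted p = 0.006836), the cathepsin B-like gene cpr-1 (log2 -1.39, adjusted p = 0.008912), the dosage compensation gene sdc-3 (log2 -1.24, adjusted p = 0.008307), tcl-2 (log2 -1.11, adjusted p = 0.0008093) and the glyoxylate cycle gene icl-1 (log2 -1.14, adjusted p = 0.02242). The call of icl-1 was lost without wild-type library 2 or 4 or double-mutant library 4 (log2 -1.15 to -1.02, highest adjusted p = 0.06433), or without double-mutant libraries 2 and 4 (adjusted p = 0.08671).

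The small heat shock protein genes hsp-16.48, hsp-16.11 and hsp-16.49 had log2 fold changes of 3.00, 2.96 and 2.96 in the double mutant over wild type (adjusted p = 0.02411, 0.01816 and 0.02614). Double-mutant library 4 held 19.4 CPM of hsp-16.49 and the other libraries of the strain at most 5.16 CPM. For hsp-16.11 these values were 14.4 and 5.42 CPM. Without that library hsp-16.48 had log2 1.90 (adjusted p = 0.05645) and hsp-16.49 had log2 1.87 (adjusted p = 0.06526). Without double-mutant libraries 2 and 4, log2 was 1.33 for hsp-16.48, 1.62 for hsp-16.11 and 1.35 for hsp-16.49 (adjusted p = 0.1401, 0.106 and 0.1574). The 3 calls were also lost with limma-voom, the sperm covariate or a fit of only these strains, with a highest adjusted p of 0.2507 for hsp-16.48, 0.1843 for hsp-16.11 and 0.2522 for hsp-16.49. Calls were also lost without wild-type libraries 2, 4 or 5 for hsp-16.48 (highest adjusted p = 0.06756), 1, 2, 4 or 5 for hsp-16.49 (0.07251) and 2 or 5 for hsp-16.11 (0.05232). These genes have near-identical copies, so their separate counts are uncertain. The gene dod-21 had log2 3.30 (adjusted p = 0.02948) and lost its call without any wild-type library or double-mutant library 5 (log2 3.16 to 3.49, highest adjusted p = 0.07912). It was also lost with limma-voom (adjusted p = 0.1664) and without double-mutant libraries 2 and 4 (adjusted p = 0.05909).

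In all, 708 genes passed, 558 higher and 150 lower in the double mutant, with 3202 at an unadjusted p under 0.05. The strains did not overlap for 997 of all genes tested (6.63%, where chance gives 0.794%) and for 576 of the 708. Upper-quartile factors gave 696 higher and 99 lower and moved the median log2 fold change of all genes from -0.0023 to 0.083, and RLE factors gave 511 higher and 169 lower. The number of genes changed was 1372 with DESeq2, 275 when only these strains were fitted, 1157 without double-mutant library 2, and 447 and 407 without double-mutant libraries 4 and 5. It was 425, 397 and 400 without wild-type libraries 2, 4 and 5.

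Of the 35 lists, 20 passed between the double mutant and wild type, 13 higher and 7 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.1487), and fry called 6. The mitochondrial dynamics and mitophagy list was lower (median log2 -0.12, adjusted p = 0.0004867, and adjusted p = 0.1487 with an estimated correlation). The list contains fndc-1, which is mutated in this strain, and was not tested without that gene. Its 2 members lower over all genes were fndc-1 and the mitophagy receptor gene dct-1 (log2 -0.94, adjusted p = 0.02672), named after its values were seen, and 3 were lower adjusted over the list alone. The UDP-glucuronosyltransferase family was higher, with 11 of 62 members higher and 27 adjusted over the list alone (median log2 0.44, adjusted p = 1.052e-09, and adjusted p = 0.1487 with an estimated correlation). The collagens were higher, with 22 of 146 members higher and 27 adjusted over the list alone (median log2 1.19, adjusted p = 6.721e-12, and adjusted p = 0.5512 with an estimated correlation). Their scores were 2.26 in double-mutant library 4 and between 0.01 and 0.68 in the other libraries of the strain. Their median was 0.19 without double-mutant library 4 (adjusted p = 4.705e-07). Without double-mutant libraries 2 and 4 the median of the collagens was -0.060 while the test still called them higher (adjusted p = 0.0003116), and medians were 0.28 for the UDP-glucuronosyltransferase family and -0.060 for mitochondrial dynamics and mitophagy. The collagens no longer passed with the sperm covariate (median log2 -0.58, adjusted p = 0.7417).

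The autophagy list was lower in the double mutant than in wild type, with 5 of 25 members lower and 11 adjusted over the list alone (median log2 -0.30, adjusted p = 1.105e-08, and adjusted p = 0.5385 with an estimated correlation). Named members were lgg-2, an LC3 family gene (log2 -0.51, adjusted p = 0.02411), atg-13 (log2 -0.31, adjusted p = 0.02246) and epg-8 (log2 -0.24, adjusted p = 0.02242). All 3 calls were lost without wild-type library 2 or 4 or double-mutant library 4. Those of atg-13 and epg-8 were also lost without wild-type library 5, those of lgg-2 and epg-8 without double-mutant library 5, and that of epg-8 without fndc-1 library 2. The highest adjusted p without these libraries was 0.07773 for lgg-2, 0.06832 for atg-13 and 0.07696 for epg-8. Without double-mutant libraries 2 and 4 none of the 3 passed (adjusted p = 0.05591 to 0.09247 for epg-8, atg-13 and lgg-2). Nor did they with upper-quartile factors (log2 -0.43 and adjusted p = 0.05917 for lgg-2, -0.23 and 0.07504 for atg-13, -0.16 and 0.1754 for epg-8) or when only these strains were fitted (adjusted p = 0.1057 to 0.1166). The call of epg-8 was lost with the sperm covariate too (adjusted p = 0.05703). The autophagy score was -0.64 in double-mutant library 2 and -0.24 in double-mutant library 4, against -0.03 to 0.02 in the other libraries of the strain, and the median log2 was -0.19 without both (adjusted p = 5.621e-06).

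The nuclear-encoded respiratory chain was higher in the double mutant than in wild type, with 4 of 42 members higher over all genes and adjusted over the list alone (median log2 0.18, adjusted p = 6.979e-07, and adjusted p = 0.5512 with an estimated correlation). Its score was 0.25 in double-mutant library 2 and 0.030 to 0.14 in the other libraries of the strain, and its median was 0.12 without that library and 0.090 without libraries 2 and 4. The complex III gene ucr-2.2 (log2 0.58, adjusted p = 0.0004257) and the complex I gene gas-1 (log2 0.46, adjusted p = 0.001628) were among them. So was the ATP synthase subunit gene asb-2 (log2 0.36, adjusted p = 0.03643), named after its values were seen. Y53G8AL.2, also a member, had log2 0.22 (adjusted p = 0.02246) and lost its call without wild-type library 2, 4 or 5 or double-mutant library 4 (highest adjusted p = 0.06288). The call of Y53G8AL.2 was also lost with RLE factors, the sperm covariate or a fit of only these strains (highest adjusted p = 0.1855). The cytosolic ribosome list was higher, with 3 of 81 members higher and 1 adjusted over the list alone (median log2 0.19, adjusted p = 3.082e-08, and adjusted p = 0.6542 with an estimated correlation). Its score was 0.61 in double-mutant library 2 and -0.06 to 0.06 in the other libraries of the strain, and its median was 0.040 without that library (adjusted p = 0.04642) and 0.078 without libraries 2 and 4. The ribosomal protein gene rpl-2 was higher (1848 ± 97.5 CPM in wild type, 3106 ± 186 CPM in the double mutant, log2 0.75, adjusted p = 0.0001992). The calls of rpl-11.2 (log2 0.65, adjusted p = 0.03406) and rpl-25.1 (log2 0.57, adjusted p = 0.04395) were lost without 8 and 12 libraries (highest adjusted p = 0.1032 and 0.1272). For rpl-11.2 these were each wild-type library, fndc-1 library 2 and double-mutant libraries 4 and 5. For rpl-25.1 they were all libraries other than wild-type 2 and double-mutant 1 and 3. Both calls were also lost without double-mutant libraries 2 and 4 (log2 0.35 and adjusted p = 0.1045 for rpl-11.2, 0.35 and 0.1893 for rpl-25.1), with the sperm covariate and when only these strains were fitted (highest adjusted p = 0.1359 and 0.1748). That of rpl-25.1 was lost with limma-voom or no filter too (highest adjusted p = 0.06135).

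The sperm list passed as higher in the double mutant with 0 of 64 members past the test over all genes or adjusted over the list alone (median log2 1.53, adjusted p = 1.409e-14, and adjusted p = 0.6136 with an estimated correlation). The sperm score was 2.303 in double-mutant library 4 and 0.052 to 0.67 in the other libraries of the strain. The median was 0.90 without that library and 0.77 without libraries 2 and 4. The germline list was lower, with 1 of 41 members lower and 0 adjusted over the list alone (median log2 -0.19, adjusted p = 9.061e-05, and adjusted p = 0.6779 with an estimated correlation). It did not pass without double-mutant library 2 (median log2 -0.06, adjusted p = 0.05663) or libraries 2 and 4 (germline median log2 -0.02, adjusted p = 0.4003). The mitochondrial unfolded protein response list did not pass (median log2 0.11, adjusted p = 0.06634), with 3 of 16 members higher over all genes and adjusted over the list alone. These, named after their values were seen, were gpd-2, a glycolytic enzyme gene (log2 0.60, adjusted p = 0.005476), and the prohibitin genes phb-1 (log2 0.39, adjusted p = 0.01124) and phb-2 (log2 0.25, adjusted p = 0.04343). The list passed without wild-type library 3, fndc-1 library 5 or double-mutant library 2 (median log2 0.12 to 0.15, adjusted p = 0.007103 to 0.0455). The mitochondrial unfolded protein response list also passed without double-mutant libraries 2 and 4 (adjusted p = 0.006003), with upper-quartile factors (median log2 0.19, adjusted p = 0.01746), limma-voom, no filter or the CPM filter (adjusted p = 0.02742 to 0.04838).

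The insulin pathway and DAF-16 targets were lower in the double mutant, with 4 of 21 members lower, and 5 lower and 1 higher adjusted over the list alone (median log2 -0.36, adjusted p = 0.001143, and adjusted p = 0.5512 with an estimated correlation). Beside mtl-1 and icl-1 these were lea-1 (log2 -0.99, adjusted p = 0.01908) and the small heat shock protein gene hsp-12.6 (log2 -1.33, adjusted p = 0.03089), named after their values were seen. The insulin list's median was -0.21 without double-mutant library 2 and -0.20 without libraries 2 and 4. The proteasome (median log2 -0.09, adjusted p = 0.001137, and adjusted p = 0.6538 with an estimated correlation) was lower. Also lower were oocyte and eggshell (median log2 -0.24, adjusted p = 1.701e-05, and adjusted p = 0.6136 with an estimated correlation) and the vitellogenins, yolk protein genes (median log2 -0.43, adjusted p = 0.0374, and adjusted p = 0.6538 with an estimated correlation). These 3 lists had 0 members past the test over all genes or adjusted over the list alone. The oocyte and eggshell score was -0.69 in double-mutant library 2 and -0.21 in library 4, against -0.025 to 0.18 in the other libraries of the strain and 0.034 to 0.23 in wild type. Its median was -0.13 without library 2 (adjusted p = 0.0007041) and -0.066 without libraries 2 and 4 (adjusted p = 0.04741). The proteasome score was -0.18 in double-mutant library 2, and the median was -0.14 without library 3 and -0.052 without libraries 2 and 4. The vitellogenins did not pass without wild-type library 3 (adjusted p = 0.0836) or double-mutant library 2 (adjusted p = 0.2227), where their score was -1.64. Mitochondrial import was higher with 0 of 15 members past either test (median log2 0.13, adjusted p = 0.0374, and adjusted p = 0.6136 with an estimated correlation). It did not pass without wild-type libraries 2 or 4 or double-mutant libraries 1 or 3 (highest adjusted p = 0.1168). The import score was 0.20 in double-mutant library 2 and 0.034 to 0.096 in the other libraries of the strain, and the median was 0.084 without that library (adjusted p = 0.04642) and 0.052 without libraries 2 and 4. Muscle was higher with 2 of 30 members higher over all genes and adjusted over the list alone (median log2 0.31, adjusted p = 0.009316, and adjusted p = 0.6538 with an estimated correlation). That call was lost without double-mutant libraries 4 or 5 (highest adjusted p = 0.08589), and the muscle median was 0.16 without libraries 2 and 4. Hypodermis and seam (median log2 0.39, adjusted p = 0.04192, and adjusted p = 0.6538 with an estimated correlation) had 2 of 20 members higher and 3 adjusted over the list alone. The moulting cycle (median log2 0.55, adjusted p = 0.04325, and adjusted p = 0.725 with an estimated correlation) had 1 of 21 higher and 1 adjusted over the list alone. Neither passed without wild-type libraries 1, 2, 3 or 4 or double-mutant library 4, nor hypodermis and seam without double-mutant library 5. Their highest adjusted p was 0.42 for hypodermis and seam and 0.8391 for the moulting cycle, whose median log2 was -0.02 without double-mutant library 4 and 0.91 without wild-type library 5. Scores in double-mutant library 4 were 1.201 for hypodermis and seam and 1.67 for the moulting cycle, above all other libraries, and the median of hypodermis and seam was 0.097 without libraries 2 and 4 (adjusted p = 0.03299). Other settings ended calls too. With upper-quartile factors the proteasome had a median log2 of -0.011 (adjusted p = 0.05515), and hypodermis and seam and the moulting cycle did not pass (adjusted p = 0.09742). With the sperm covariate none of proteasome, hypodermis and seam, moulting cycle, muscle and vitellogenins passed (adjusted p = 0.05516 to 0.5315). Nor did mitochondrial import with RLE factors or DESeq2 (highest adjusted p = 0.07547), the vitellogenins with DESeq2 or the CPM filter (0.1027), or the moulting cycle and the vitellogenins without double-mutant libraries 2 and 4 (0.2768 and 0.5943).

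Between the double mutant and fndc-1, the F-box gene fbxa-192 (0.496 ± 0.0869 CPM in fndc-1, 8.93 ± 1.22 CPM in the double mutant, log2 4.16, adjusted p = 2.397e-10) and the metallothionein gene mtl-1 (log2 1.55, adjusted p = 0.006575), both lower in fndc-1 than in wild type, were higher in the double mutant. The scramblase gene scrm-4 (log2 1.78, adjusted p = 5.115e-07), catp-3 (log2 1.24, adjusted p = 0.008898), the aspartyl protease gene asp-17 (log2 1.15, adjusted p = 0.01341) and dod-24 (log2 1.28, adjusted p = 0.01878) were also higher. Lower were tep-1 (log2 -1.67, adjusted p = 0.002059), set-10 (log2 -1.53, adjusted p = 8.67e-07), cyn-5 (log2 -1.31, adjusted p = 2.497e-06), the zinc transporter gene zipt-1 (log2 -1.16, adjusted p = 4.271e-07), the synaptotagmin gene snt-2 (log2 -1.07, adjusted p = 0.0001016) and the T-box gene tbx-2 (log2 -1.05, adjusted p = 0.002619). The call of asp-17 was lost without fndc-1 library 5 or double-mutant library 5 (highest adjusted p = 0.05169). That of dod-24 was lost without fndc-1 libraries 2, 4 or 5 or double-mutant library 1 (highest adjusted p = 0.07062) and without double-mutant libraries 2 and 4 (adjusted p = 0.05017). When only these strains were fitted dod-24 and catp-3 did not pass (adjusted p = 0.08204 and 0.05959), nor did mtl-1 with limma-voom (adjusted p = 0.05548). In all, 147 genes passed, 111 higher and 36 lower in the double mutant, with 1719 at an unadjusted p under 0.05. The strains did not overlap for 634 of all genes tested (4.22%, where chance gives 0.794%) and for 145 of the 147. DESeq2 called 363 genes changed.

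Of the 35 lists, 18 passed between the double mutant and fndc-1, 15 higher and 3 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.6252), and fry called 1, the nuclear-encoded respiratory chain. That list was higher in the double mutant, with 1 of 42 members higher and 6 adjusted over the list alone (median log2 0.19, adjusted p = 5.071e-09, and adjusted p = 0.6252 with an estimated correlation). Its median was 0.10 without double-mutant libraries 2 and 4. The member was the succinate dehydrogenase gene mev-1 (log2 0.27, adjusted p = 0.04376), whose call was lost without any library other than wild-type 1 and double-mutant 2 and 3 (log2 0.25 to 0.29, highest adjusted p = 0.2501). With all the other settings run except DESeq2, mev-1 did not pass either (highest adjusted p = 0.269). The mitochondrial unfolded protein response list was higher, with 1 of 16 members higher and 5 adjusted over the list alone (median log2 0.17, adjusted p = 0.01141, and adjusted p = 0.6252 with an estimated correlation). It did not pass without double-mutant library 3 (median log2 0.15, adjusted p = 0.05199). The member was timm-23, a gene of the mitochondrial import machinery (log2 0.36, adjusted p = 0.03012), named after its values were seen. Its score was -0.21 in double-mutant library 2 and 0.11 to 0.19 in the other libraries of the strain.

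The antimicrobial and pathogen response list was higher in the double mutant than in fndc-1, with 4 of 42 members higher and 6 adjusted over the list alone (median log2 0.34, adjusted p = 2.738e-05, and adjusted p = 0.6252 with an estimated correlation), and its score was 0.74 in double-mutant library 2. Its score was -0.49 and -0.78 in fndc-1 libraries 4 and 5 and 0.040 to 0.17 in fndc-1 libraries 1, 2 and 3. The median of this list was 0.21 without double-mutant library 2 (adjusted p = 0.0177) and 0.12 without libraries 2 and 4. The cytosolic ribosome list was higher, with rpl-2 (log2 0.74, adjusted p = 0.0001678) the only one of 81 members past the test, over all genes or adjusted over the list alone (median log2 0.22, adjusted p = 2.804e-12, and adjusted p = 0.6252 with an estimated correlation). The collagens were higher with 0 of 146 members past the test over all genes and 12 adjusted over the list alone (median log2 1.12, adjusted p = 1.395e-15, and adjusted p = 0.6252 with an estimated correlation). The median of the cytosolic ribosome was 0.059 without double-mutant library 2 and 0.092 without libraries 2 and 4. That of the collagens was 1.71 without fndc-1 library 4, 0.36 without double-mutant library 4 and 0.18 without double-mutant libraries 2 and 4.

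Further lists were higher in the double mutant than in fndc-1. The UDP-glucuronosyltransferase family had 2 of 62 members higher and 7 adjusted over the list alone (median log2 0.19, adjusted p = 1.592e-05, and adjusted p = 0.6252 with an estimated correlation). The cytochrome P450 family was higher with 1 of 64 members lower, and 4 higher and 1 lower adjusted over the list alone (median log2 0.20, adjusted p = 0.00512, and adjusted p = 0.6252 with an estimated correlation). The mitochondrial ribosome (median log2 0.14, adjusted p = 2.852e-07, and adjusted p = 0.6252 with an estimated correlation) was higher. So were the mitochondrial genome (median log2 0.30, adjusted p = 0.01625, and adjusted p = 0.6252 with an estimated correlation) and sperm (median log2 0.84, adjusted p = 9.98e-06, and adjusted p = 0.7576 with an estimated correlation). These 3 lists had 0 members past the test over all genes or adjusted over the list alone. The mitochondrial ribosome score was 0.27 in double-mutant library 2 and -0.024 to 0.066 in the other libraries of the strain, and the median was 0.064 without that library (adjusted p = 0.0003834) and 0.058 without libraries 2 and 4. The sperm median was 1.31 without fndc-1 library 4 and 0.24 without double-mutant library 4 (adjusted p = 0.02681). The median was 0.11 for the UDP-glucuronosyltransferase family without double-mutant library 4, and for the cytochrome P450 family 0.10 without fndc-1 library 5 and 0.097 without double-mutant libraries 2 and 4. Glycolysis had 0 of 19 members past the test over all genes and 3 higher adjusted over the list alone (median log2 0.10, adjusted p = 0.01749, and adjusted p = 0.6252 with an estimated correlation). Glycolysis lost its call without double-mutant libraries 3 or 5 (highest adjusted p = 0.1138). Mitochondrial import had 1 of 15 members higher over all genes and adjusted over the list alone (median log2 0.14, adjusted p = 0.01557, and adjusted p = 0.6252 with an estimated correlation). Mitochondrial import lost its call without fndc-1 library 3 (adjusted p = 0.0622), and its median was 0.071 without double-mutant library 2 and 0.082 without libraries 2 and 4. The C-type lectin family had 3 of 129 higher and 9 adjusted over the list alone (median log2 0.15, adjusted p = 0.01315, and adjusted p = 0.6492 with an estimated correlation). It did not pass without fndc-1 library 5 or double-mutant library 2 (highest adjusted p = 0.1458). Neuron had 1 of 43 higher and 7 adjusted over the list alone (median log2 0.16, adjusted p = 0.01625, and adjusted p = 0.6747 with an estimated correlation). Neuron lost its call without double-mutant libraries 4 or 5 (highest adjusted p = 0.2273).

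Autophagy was lower in the double mutant than in fndc-1 (median log2 -0.12, adjusted p = 0.0003028, and adjusted p = 0.6252 with an estimated correlation). Also lower were germline (median log2 -0.13, adjusted p = 9.98e-06, and adjusted p = 0.6747 with an estimated correlation) and oocyte and eggshell (median log2 -0.12, adjusted p = 0.01625, and adjusted p = 0.8102 with an estimated correlation). These lists had 0 members past the test over all genes, and adjusted over the list alone 2 autophagy members were lower. Germline scores were 0.18 and 0.22 in fndc-1 libraries 4 and 5 and -0.063 to -0.017 in fndc-1 libraries 1, 2 and 3. The autophagy median was -0.063 without double-mutant library 2. Without double-mutant library 3 it was -0.20 for autophagy, -0.21 for germline and -0.22 for oocyte and eggshell, and -0.18 for the last without double-mutant library 1. Germline did not pass without double-mutant library 2 (median log2 -0.03, adjusted p = 0.08092), nor oocyte and eggshell without fndc-1 libraries 4 or 5 or double-mutant libraries 2 or 4 (highest adjusted p = 0.6167). Without double-mutant libraries 2 and 4 autophagy did not pass either (median log2 -0.05, adjusted p = 0.2853), nor sperm (median log2 0.12, adjusted p = 0.1033). The same held for germline (median log2 0.0073, adjusted p = 0.7515), oocyte and eggshell (median log2 0.06, adjusted p = 0.06651), the mitochondrial genome (adjusted p = 0.1011), the C-type lectin family (adjusted p = 0.1033) and neuron (adjusted p = 0.1516). With the sperm covariate oocyte and eggshell (adjusted p = 0.0851) and glycolysis (adjusted p = 0.07438) did not pass. Nor did glycolysis when only these strains were fitted (adjusted p = 0.07271) or the C-type lectin family with no filter (adjusted p = 0.1995).

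Genes past the threshold in both mutants against wild type, in the same direction, numbered 157, of which 127 were higher and 30 lower. Higher in both were dct-17 and pqn-75, the aquaporin gene aqp-4 (log2 0.70 in fndc-1 and 0.63 in the double mutant), the sugar transporter gene swt-3 (0.84 and 1.58), the bestrophin gene best-17 (0.86 and 1.06) and eppl-1 (0.56 and 0.77). Lower in both were fndc-1, fmo-5 (-0.91 and -0.79), the cytochrome P450 genes cyp-25A3 (-1.203 and -0.96) and cyp-29A4 (-1.72 and -1.39), mtl-1 (-2.83 and -1.28) and the nuclear hormone receptor gene nhr-236 (-1.39 and -1.26). In the double mutant mtl-1 and nhr-236 did not pass when only these strains were fitted (adjusted p = 0.06236 and 0.05019). Independent lists of these sizes would share 6.61 higher and 1.03 lower genes. Strains simulated as unchanged from wild type shared 0, but with 0 genes called in fndc-1 in any of these simulations this was fixed and is no comparison for the 157. Across genes, which are not independent replicates, the fold changes had r = 0.491, and the simulated r from the shared wild-type libraries was 0.504. The covariance was 0.150 and the simulated one 0.064. With the wild-type libraries divided between the comparisons, a mean of 32.9 genes were shared (14 to 151), r averaged 0.305 and the covariance 0.115. The number of shared calls was 463 with DESeq2, 376 with the sperm covariate, 398 without double-mutant library 2 and 314 without double-mutant libraries 2 and 4. It was 83, 71 and 90 without wild-type libraries 2, 4 and 5, 83, 77 and 81 without fndc-1 libraries 1, 2 and 3, and 99 without double-mutant library 5.

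Genes that changed in fndc-1 and changed the opposite way in the double mutant against fndc-1 numbered 61, of which 23 were higher and 38 lower in fndc-1. Higher in fndc-1 were cyn-5, zipt-1 (log2 0.95), set-10, klu-1 (log2 1.62), snt-2 (log2 1.00) and pad-2 (log2 0.69). Lower were fbxa-192, fbxa-111 (log2 -1.997), mtl-1, mtl-2, nhr-131 and set-28, which had 26 counts over wild type and 0 over fndc-1. Of these genes, cyn-5, zipt-1, set-10 and klu-1 lie at the right end of chromosome I and set-28 at the left end of chromosome X, in the regions described below. The nuclear hormone receptor gene nhr-131 (chromosome V, 494370 to 497297) had 4.62 ± 1.19 CPM in wild type, 4.51 ± 0.640 CPM in the double mutant and 0 counts in the 5 fndc-1 libraries, at least 391.8-fold lower than wild type with a floor of 3 counts over the strain. Such floors cover counting error only. The gene fbxa-192 had a similar pattern, with 6.77 CPM in wild type, 0.496 CPM in fndc-1 and 8.93 CPM in the double mutant. The double mutant carries the same fndc-1 allele. Whether a difference of the fndc-1 stock other than that allele underlies the values of nhr-131 and fbxa-192 was not tested. The call of mtl-2 between the double mutant and fndc-1 (log2 0.68, adjusted p = 0.0259) was lost without fndc-1 libraries 1, 2, 3 or 5 or double-mutant library 5 (highest adjusted p = 0.1196), with upper-quartile factors (adjusted p = 0.05159) and when only these strains were fitted (adjusted p = 0.08297). Independent lists would share 0.426 and 0.761 genes. In a separate set of simulations, with all strains at the fndc-1 level, 0 genes were opposed, but with at most 1 gene called between fndc-1 and wild type in any of them this is no comparison for the 61. The fold changes had r = -0.421 (simulated -0.500) and a covariance of -0.123 (simulated -0.063). With the fndc-1 libraries divided, a mean of 39.6 genes were opposed (33 to 45), r averaged -0.284 and the covariance -0.087.

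Opposed genes were grouped by position, a feature chosen after the values were seen. At the left end of chromosome X (42632 to 286216), 17 of 19 tested genes were lower in fndc-1 than in wild type, 11 of them with 0 counts in the 5 fndc-1 libraries, and 1 of the 19 differed between the double mutant and wild type. Among them, Y73B3A.4 had 23.7 ± 1.61 CPM in wild type, 21.5 ± 7.25 CPM in the double mutant and 0 counts in fndc-1, at least 2029-fold lower than wild type with the same floor. At the right end of chromosome I (14961497 to 15058994), 13 of 18 tested genes were higher in fndc-1, with a median log2 of 1.31 over the 18, and 0 of the 18 differed between the double mutant and wild type. All 30 of these genes changed the opposite way between the double mutant and fndc-1. Without the genes of both ends, 30 opposed calls were counted. Some of these genes, such as cyn-5 and F31C3.2 (15036009 to 15040537), overlap a neighbour, and reads in the overlap cannot be assigned with certainty.

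**Figure D3:**
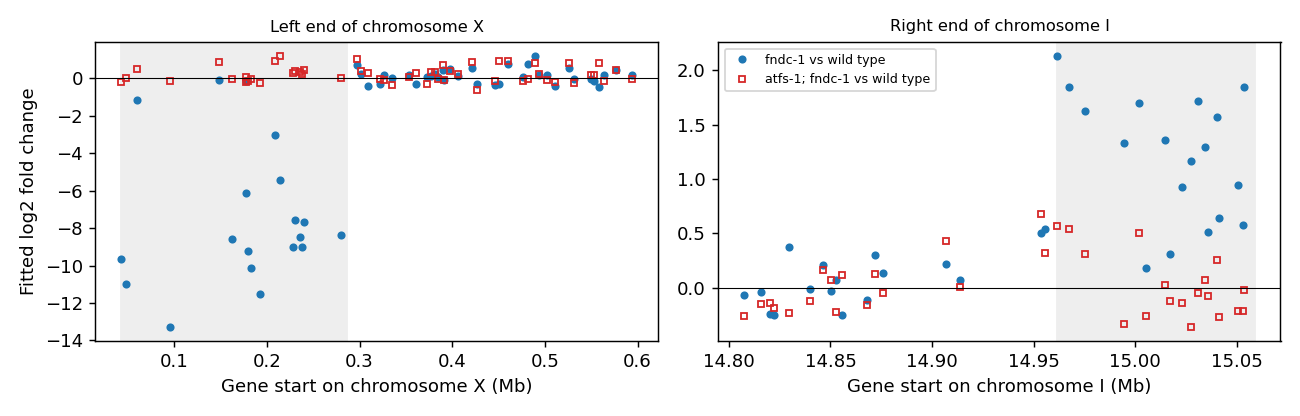
Fitted log2 fold change against wild type (y axis) of each tested gene by its start in Mb (x axis) at the left end of X and the right end of I; filled circles are fndc-1, open squares the double mutant, and the shaded parts are the regions given in the text. In the shaded part of X, 17 of 19 genes are lower in fndc-1, and in that of I, 13 of 18 are higher, while fitted values of genes with 0 counts depend on the prior count.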

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

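The tests of the loss and gain of chromosome ends, of scattered regulation, of depth for the genes at 0 counts, of the sperm and embryo scores, and of the depth, top genes and strain of double-mutant library 2 were chosen after the result was seen. The tests of other chromosome ends, of the sperm score against depth, of transcript length and of other splits of the samples were written before their results.

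By Dixon's test, a library far from the other 4 of its strain was found in 28 of 288 groups. Chance gives about 1 in 20 where values are normal and groups independent. The groups here, CPM of named genes and list scores, are not independent, so that rate is only a rough guide. Of the 28, double-mutant library 2 held 10, double-mutant library 4 another 10 and wild-type library 1 held 3. Wild-type library 2 and fndc-1 libraries 1, 3, 4 and 5 held 1 each. In double-mutant library 2 the CPM was 10.16 for fndc-1, 319.3 for hsp-6, 265.7 for hsp-60, 505.9 for cyn-5 and 9.04 for sdc-3. Its list scores were -0.208 for the mitochondrial unfolded protein response, -0.408 for the tricarboxylic acid cycle, 0.737 for antimicrobial and pathogen response, 0.607 for the cytosolic ribosome and -0.792 for germline. In double-mutant library 4 the CPM was 16.06 for mtl-1, 2.003 for cyp-25A1, 19.56 for hsp-16.48, 19.42 for hsp-16.49, 390.5 for cpr-1 and 63.26 for ugt-47. Its list scores were 1.67 for the moulting cycle, 2.303 for sperm, -0.735 for embryo and 1.201 for hypodermis and seam. Wild-type library 1 had 13.14 CPM of aqp-4, 1.40 CPM of klu-1 and a histone score of 0.156, and wild-type library 2 had 92.39 CPM of zipt-1. The fndc-1 libraries had 5.80 CPM of pqn-75 in library 1, an endoplasmic reticulum stress score of 0.0755 in library 3, 0.650 CPM of fbxa-192 in library 4 and a C-type lectin score of -0.371 in library 5.

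At the left end of X and the right end of I, 30 genes changed in fndc-1 and changed back in the double mutant, which carries the same fndc-1 allele. Scattered regulation through FNDC-1 and ATFS-1 is argued against by 17 opposed genes among 20 neighbours, where the highest of the random placements was 4 (permutation p = 0.0001, the smallest they can give). A general change at chromosome ends is argued against by 0 of the other 10 ends with a median beyond 0.3 on the log2 scale, and depth by a median of 310.7 counts that the wild-type level would give for the 11 genes at 0. A loss of the X end and a gain of the I end in the fndc-1 stock stays open: of 18 genes with at least 5 CPM in wild type, 94.44% had all fndc-1 libraries apart from the other 10 in the direction of their region, but the bounds were set from the same values, no DNA was analysed here, and regulation of these regions as blocks was not tested. Against a loss of the whole X region, Y73B3A.18 kept 6.89 CPM in fndc-1 (15.4 CPM in wild type), T08D2.4 had 0.801 CPM (0.881 CPM in wild type) and Y73B3A.11 had 0.417 CPM (0.447 CPM in wild type). However, T08D2.4 (177396 to 177856) lies within T08D2.5 (177375 to 179394), which had 492 counts over wild type and 6 over fndc-1. Reads of T08D2.4 therefore cannot be assigned with certainty. At the I end the share above covers direction only, not size. There log2 ranged from 0.18 in pole-1 (adjusted p = 0.785) to 2.13 in ces-2 (adjusted p = 0.0651), with 13 of 18 genes past the test. Whether these values go with a uniform gain of the I end was not tested.

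The spread of sperm genes within strains ran against embryo genes, with r = -0.855 (permutation p = 0.00013, adjusted p = 0.000195 over 3 relations) and rho = -0.714 (permutation p = 0.00312) over 15 libraries centred on their strain, and r = -0.764 without the 2 farthest libraries. Within wild type, fndc-1 and the double mutant r was -0.843, -0.954 and -0.934. Transcript length is argued against by rho = -0.0171 over 14842 genes between loading on the first component and length, and depth stays open, with r = 0.128 for the total count (rho = 0.1, permutation p = 0.7137 and 0.7657, adjusted p = 0.7137, and r = 0.357 without the 2 farthest libraries) and r of -0.357, 0.943 and 0.456 within wild type, fndc-1 and the double mutant. Cultures at different points of adult development are a candidate explanation, and collagens moved with sperm genes (r = 0.884, rho = 0.779, permutation p = 5e-05 and 0.00424, adjusted p = 0.00015, r = 0.833 without the 2 farthest libraries). Whether the strains themselves differ in developmental timing stays open.

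Double-mutant library 2 had a rho of -0.688 over genes between transcript length and its ratio to the other libraries of its strain, and the next largest in size among the other 14 libraries was 0.485, in double-mutant library 3, whose reference includes library 2. Wild-type libraries 1 and 5, compared only with other wild-type libraries, had rho of -0.415 and 0.422, so sizable differences by length also occurred within wild type. A library of another strain is argued against by 10.16 CPM of fndc-1, near the mutants, and by 5 of 5 abundant X end genes being present. Depth is argued against by its total of 50.86 M counts, inside the range of the others, and a few dominant genes by a share of 5.71% in its top 10 genes, where the highest of the other libraries was 11.76%. A bias by transcript length or RNA quality may account for this library, and which of them was not tested. No biological explanation was tested for a library that differs from its own strain.

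Other splits of the samples were drawn 100 times for each comparison, the real one included. For fndc-1 against wild type, 1 of 100 splits gave as many as the real 281 genes, and the highest other gave 0. For the double mutant against wild type, 1 of 100 gave as many as 708, and the highest other gave 1. The real split thus gave the most genes in both, at the smallest share that 100 splits can give. Splits that mix the strains carry any strain difference in their spread, which lowers their counts. These counts therefore do not exclude a structure of the samples other than strain. For the double mutant against fndc-1, 2 of 100 splits gave as many as 147 genes, the real one and another that gave 591. This share is under 0.05, but a split that mixes the strains gave more genes than the real one. The splits therefore do not exclude an origin of the 147 other than strain. That split set fndc-1 libraries 1, 2 and 3 with double-mutant libraries 2 and 5 against the rest, which points to a structure of the samples other than strain.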

How the results depend on the processing

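The sperm covariate, leaving out double-mutant libraries 2 and 4 and leaving out the genes of the chromosome ends were chosen after seeing the data; the other settings were planned. Below, the number of genes changed is given for fndc-1 against wild type, then the double mutant against wild type, then the double mutant against fndc-1, and the cause of each change was not tested. DESeq2 called 784, 1372 and 363 genes changed and 463 shared calls. With only the strains compared in the fit there were 575 and 275 genes changed for the comparisons with wild type, and atfs-1 between the mutants lost its call (log2 -0.3433, adjusted p = 0.0525). Without double-mutant libraries 2 and 4, 1116 genes changed in fndc-1, shared calls were 314, and atfs-1 in fndc-1 passed (log2 -0.1646, adjusted p = 0.04313). With the sperm covariate 630 genes changed in fndc-1, shared calls were 376 and 10 lists passed in fndc-1, with the sperm list lost by construction, since the covariate is its own score. Without the genes of the chromosome ends, which held 17 opposed calls at X and 13 at I, 30 opposed calls were left.

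In the lists, an estimated correlation left 0, 0 and 0 gene lists changed and fry 1, 6 and 1. The oocyte and eggshell list, lower in the double mutant than in fndc-1, was at 0.06026 without double-mutant libraries 2 and 4 (adjusted p = 0.06651). With the sperm covariate the collagens in fndc-1 against wild type were at -0.8449 (adjusted p = 0.0002143), the embryo list in the double mutant against wild type at 0.3124 (adjusted p = 0.007858) and the sperm list between the mutants at -0.0272 (adjusted p = 0.7839), the last fixed by the covariate and no test of that list. Whether replicate numbers pair the samples stays open. Same-numbered pairs correlated from -0.5915 to 0.6645, with 7 of 15 over 0.1. Their mean was 0.1273, against -0.02565 for pairs with different numbers, and 6 of 15 libraries correlated best with their own number. With the replicate block, 155 and 507 genes changed for the comparisons with wild type, shared calls were 83, and atfs-1 between the mutants was at -0.308 (adjusted p = 0.0698).

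Leaving out single libraries gave 146 to 736, 397 to 1157 and 106 to 161 genes changed, 71 to 398 shared calls and 50 to 73 opposed calls. The gene lists changed ranged from 13 to 17, 17 to 22 and 16 to 19, and atfs-1 between the mutants from -0.3417 to -0.2831. For named genes, leaving out single libraries kept the direction and side of the threshold in 1245 values and gained a call in 1, and the others lost it. Lists kept both in 1487 values, lost the call in 53 and gained it in 35. Under the other settings named genes kept both in 901 values, lost the call in 76 and gained it in 1, and lists in 1083, 152 and 21, with 4 reversed. These counts include 2 losses and 1 reversal of the sperm list that the sperm covariate fixes. In the simulated data, with changes placed only in genes above about 1 CPM in wild type, 29%, 30% and 31% of the 1.5-fold changes were found in the 3 comparisons. Changes of that size can therefore be missed.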

Other observations

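The alternatives reported here without double-mutant libraries 2 and 4 were chosen after the result was seen, and the lists were fixed before. The glutathione S-transferase family, enzymes that conjugate toxins, was higher in the double mutant than in wild type, with 5 of 37 members higher, and 8 higher and 1 lower adjusted over the list alone (median log2 0.27, adjusted p = 7.958e-05, and adjusted p = 0.6136 with an estimated correlation). The median was 0.16 without double-mutant library 2 (adjusted p = 0.02931) and 0.12 without libraries 2 and 4. Between the double mutant and fndc-1 it was also higher, with 0 members past the test (median log2 0.29, adjusted p = 8.371e-05, and adjusted p = 0.6252 with an estimated correlation), and did not pass without double-mutant library 2 (median log2 0.14, adjusted p = 0.1627), whose score was 0.73, or without double-mutant libraries 2 and 4 (adjusted p = 0.2279). The C-type lectin family was higher in the double mutant than in wild type, with 14 of 129 members higher, and 17 higher and 2 lower adjusted over the list alone (median log2 0.31, adjusted p = 7.958e-05, and adjusted p = 0.5512 with an estimated correlation), and the median was 0.18 without double-mutant libraries 2 and 4. The cytosolic heat shock list was higher there too, with 7 of 17 members higher and 1 lower, and 9 higher and 1 lower adjusted over the list alone (median log2 2.07, adjusted p = 0.01179, and adjusted p = 0.5512 with an estimated correlation), and its score was 1.76 in double-mutant library 4. The heat shock median was 1.26 without that library and 1.19 without libraries 2 and 4.

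The tricarboxylic acid cycle list did not pass between the double mutant and wild type (median log2 0.08, adjusted p = 0.2727), with 1 of 20 members higher over all genes and adjusted over the list alone. It passed as higher without double-mutant library 2 (median log2 0.16, adjusted p = 5.706e-05) and without double-mutant libraries 2 and 4 (median log2 0.13, adjusted p = 7.371e-05), and with upper-quartile factors (median log2 0.16, adjusted p = 0.0168). The mitochondrial ribosome list did the opposite, higher with all libraries (median log2 0.09, adjusted p = 0.002466, and adjusted p = 0.725 with an estimated correlation) and not passing without double-mutant library 2 (median log2 0.02, adjusted p = 0.3131) or libraries 2 and 4 (adjusted p = 0.4381). Without wild-type library 1 its median was 0.13. It had 2 of 71 members higher and 0 adjusted over the list alone. The hypoxia response list was higher in fndc-1 than in wild type, with 1 of 13 members higher and 3 adjusted over the list alone (median log2 0.11, adjusted p = 0.03028, and adjusted p = 0.7148 with an estimated correlation). The hypoxia score was 0.16 to 0.35 in fndc-1 libraries 1, 2 and 3 and -0.091 and -0.15 in fndc-1 libraries 4 and 5. The median was 0.19 without wild-type library 1 or fndc-1 library 4 and 0.23 without fndc-1 library 5. It did not pass without wild-type library 2 or 4, fndc-1 library 2 or 3, or double-mutant library 2 (median log2 0.01 to 0.12, highest adjusted p = 0.09455), nor without double-mutant libraries 2 and 4 (adjusted p = 0.06185) or when only these strains were fitted (adjusted p = 0.07392). In the double mutant against wild type the hypoxia list was just short of the threshold (median log2 0.19, adjusted p = 0.05108), again with 1 member higher and 3 adjusted over the list alone. There it passed when any of 7 single libraries was left out (adjusted p = 0.01731 to 0.04909). Between the double mutant and fndc-1 its median log2 was 0.0003 (adjusted p = 0.9829).

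Outside the chromosome ends, 1 gene had 0 counts in all wild-type libraries and a mean of at least 1 CPM in both mutant strains. C32H11.9 (chromosome IV, 12935011 to 12936271), chosen after its values were seen, had 2.57 CPM in fndc-1 and 4.72 ± 3.25 CPM in the double mutant, at least 218.7-fold higher in fndc-1 than in wild type with a floor of 3 counts over the strain. It lies beside dod-21 (12936738 to 12937988) and near dod-24 (12940106 to 12941354), and reads shared between similar neighbours were not examined. The neighbour dod-21 had 0 counts in fndc-1 library 5 and 158 to 365 counts in the other libraries of that strain.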
